A study of Homo sapiens with 12 samples.

How the data were processed

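Total RNA of 12 samples of the human breast cancer cell line MDA-MB-231 was labelled with biotin and hybridized to arrays that carry 28869 probe sets, each for a transcript cluster. The samples fall into 4 groups of 3: no treatment, 0.1 mM 5-aminolevulinic acid (5-ALA), 0.1 mM 5-ALA with 15 nM of an siRNA against FECH, and 0.1 mM 5-ALA with 15 nM of a commercial control siRNA. The FECH siRNA is a single sequence of 19 nucleotides, gaauauccucuugguuccg. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these samples and no more.

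According to the submitters' processing notes, the signals were made with RMA in the oligo package, which corrects for background, brings the arrays to a common distribution and summarises the probes of each probe set. The versions of RMA and oligo and the genome build are not given in the sources used here. The deposited signal values are in the unit intensity, on a linear scale from 21.0 to 23641. The deposited workbook holds 12 further columns of values per sample, whose names give a group but not which sample, and these were not used. The deposited value table of the series differs from the deposited workbook by at most 5e-05 on the linear scale. The design had foreseen log2 values as deposited. The signals were linear, so their log2 was taken here, with a pseudocount of 0. No further normalization was applied.

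Of the 28869 probe sets, 6741 carry no gene symbol and 2191 carry several. These were left out of the gene tests and were tested apart. The remaining 19937 carry 1 symbol. Of these, 19309 were brought to current symbols by their Entrez gene number and 628 kept the name in the file, and 27 symbols that a spreadsheet had turned into date numbers were restored. Genes were kept when a probe set was above the median of all probe sets, 7.29 on the log2 scale, on at least 3 of the 12 arrays, and the probe set with the highest mean stood for each symbol. This left 12151 genes. No detection values were in the tables used, so a group mean below this level is not shown to be above background, and the fold of such a gene is a ratio of signals.

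Differences between groups were tested with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for data handling. One mean per group was fitted over all 12 arrays, so that the 4 groups shared 1 estimate of the spread, and eBayes was run with its defaults. The p-values are two-sided, and were adjusted by the Benjamini-Hochberg method within each comparison. Genes with an adjusted p below 0.05 count as past the test. The 4 comparisons fixed before the data were examined are FECH siRNA against control siRNA, 5-ALA against no treatment, control siRNA against 5-ALA only, and FECH siRNA against 5-ALA only. The comparisons of both siRNA groups with no treatment were added after the data had been seen. For FECH itself, an exact permutation test of 3 against 3 values was run as well.

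The 30 gene lists were also fixed before the data were examined. They cover heme and iron, stress responses, inflammation, the cell cycle, lipid and energy metabolism, the respiratory chain, lysosomes, cell state, small RNA silencing, histones and markers of other cell types. Of their 624 symbols, 583 have a probe set and 518 were tested. The 29 lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. Camera asks whether a list moved relative to the other genes, and fry whether its members moved on balance one way.

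The genes named in the text follow a rule fixed before the data were examined. It takes FECH, the heme biosynthesis genes, HMOX1, TFRC and ABCG2. It adds, among the genes past the test whose groups do not overlap, the 10 with the largest rise and the 10 with the largest fall, leaving out noncoding and provisional names. From each list it takes up to 4 members past the test with the largest change, or the member with the lowest p where none passed. Where fewer than 3 genes passed in a direction, it adds the 5 genes with the lowest p in that direction, given as not past the test. Any other gene is named with the words that it was chosen after its values were seen.

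The sample numbers in the titles run in 3 blocks, each with 1 sample of every group, and it was checked whether they pair the samples. After the group means were removed, samples of different groups in the same run of numbers correlated at 0.207 to 0.539, and those in different runs at 0.154 or below. The best partner in another group came from the same run in 12 of 12 samples. The planned fit had no block, and a fit with these runs as a block was planned as an alternative. Its value stands beside a result where it changed a call, or a count by more than 1.5 times.

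The other alternatives were no filter, a filter at the 70th percentile, trended and robust variance, a fit of only the groups compared, the other deposited table, cyclic loess between arrays, centring of each array on its median, all probe sets, array weights, and leaving out each array in turn. Leaving out untreated replicate 3 from the comparisons it is not part of was added after the data had been seen.

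The fit was tested on simulated data with 12151 genes, in which 200 were changed by a known amount. A change of 0.5 on the log2 scale was recovered in 80.6% of the changed genes for FECH siRNA against control siRNA and in 88.1% for 5-ALA against no treatment. A log2 change of 1 was recovered in 100% in each of the 4 comparisons, and a change of 2 in 98.5% for FECH siRNA against control siRNA and in 100% in the others. Of the genes called, 7% were false for FECH siRNA against control siRNA, 6.80% for 5-ALA against no treatment, 7.66% for control siRNA against 5-ALA only and 4.46% for FECH siRNA against 5-ALA only. The simulated noise was independent between arrays, with the same spread of a gene on every array. It lacked the correlation within runs of sample numbers, so these rates may not hold for the real arrays. The simulations set beside comparisons that share arrays were drawn with such independent noise too.

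Transcript and genome sequences were not used here, so the siRNA was not searched for matches in other transcripts, and no positions are given.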

Results

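Transcript levels were measured on arrays in 12 samples of MDA-MB-231, an established human breast cancer cell line, in 4 groups of 3. One group was untreated, and the other 3 received 0.1 mM 5-ALA, the precursor from which cells make heme. Of these, 1 group received 5-ALA only, 1 was also transfected with 15 nM of an siRNA against FECH, and 1 with 15 nM of a control siRNA. FECH encodes ferrochelatase, the mitochondrial enzyme that inserts iron into protoporphyrin IX in the last step of heme synthesis. The median log2 signal per array lay between 7.25 and 7.34. Log2 signals of arrays of the same group correlated across genes at 0.985 to 0.996 and those of different groups at 0.953 to 0.997, where genes are not independent replicates. The first principal component held 60.2% of the variance and set the FECH siRNA arrays, at 27.1 to 29.6, apart from the other 9, at -11.0 to -8.05. The number of arrays limits the precision of every value below.

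FECH mRNA was lower in the FECH siRNA group than in each of the others. Its log2 signal (probe set 8023466) was 8.49 ± 0.09 (SD, n = 3) in untreated cells, 8.50 ± 0.12 (SD, n = 3) with 5-ALA only, 8.55 ± 0.05 (SD, n = 3) with control siRNA and 6.53 ± 0.09 (SD, n = 3) with FECH siRNA. Against control siRNA this is 4.06-fold lower, or 24.7% of the control level (limma adjusted p = 1.7e-09), and against 5-ALA only it is 25.5% (limma adjusted p = 2.5e-09). The signal with FECH siRNA lay below the filter level of 7.29 and is not shown to be above background, so these are ratios of signals, in which background would hide part of a fall. The exact permutation test of 3 against 3 values gave a two-sided p of 0.1 against control siRNA, the smallest p this design allows.

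**Figure D1:**
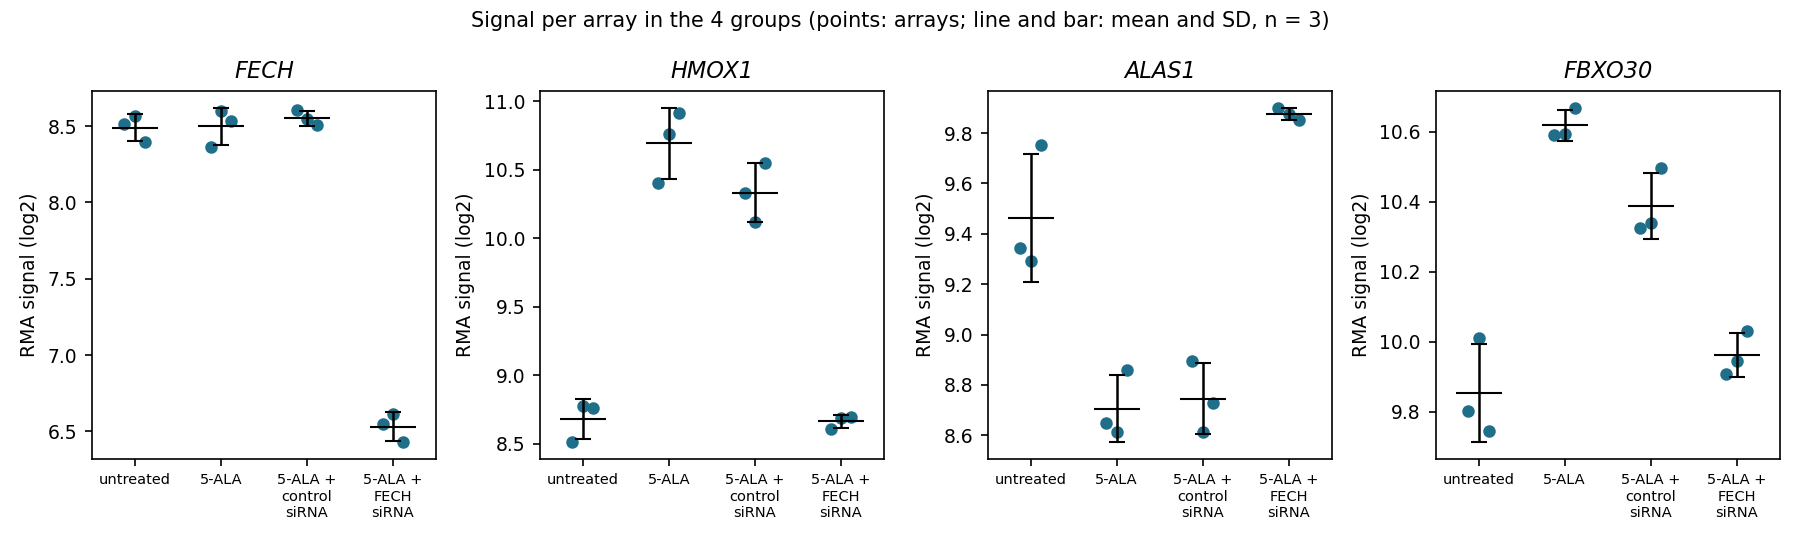
Log2 RMA signal of FECH, HMOX1, ALAS1 and FBXO30 in each array (points) of the 4 groups, with the mean and SD of 3 arrays; each panel has its own vertical axis, which does not start at 0. FECH stood at 6.53 with FECH siRNA and between 8.49 and 8.55 in the other groups, and HMOX1 was high with 5-ALA only (10.69) and with control siRNA (10.33).

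The comparison of FECH siRNA with control siRNA asks what changes when FECH is targeted, since both groups had 5-ALA and the same siRNA dose. HMOX1, the heme oxygenase that breaks heme down, fell from 10.33 ± 0.22 to 8.66 ± 0.05 on the log2 scale (SD, n = 3; probe set 8072678), 3.18-fold lower (limma adjusted p = 4.2e-07). ALAS1, the first and rate-limiting enzyme of heme synthesis, rose from 8.75 ± 0.14 to 9.88 ± 0.02 (SD, n = 3; probe set 8080184), 2.19-fold higher (limma adjusted p = 4.0e-06). TFRC, the transferrin receptor through which cells take up iron, rose 1.25-fold (limma adjusted p = 0.0080). Outside heme and iron, the collagenase MMP1 rose 4.03-fold and the immediate early transcription factor EGR1 rose 4.09-fold, while the integrin ITGA6 fell, 3.58-fold lower, and the spindle checkpoint protein MAD2L1 fell, 4.02-fold lower.

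The largest rises in signal were those of AWAT2, a wax ester synthase, at 6.06-fold (log2 fold change 2.60, SE 0.12), and the receptor MRGPRX4 at 5.56-fold (2.48, SE 0.09). HHIP, which binds hedgehog proteins, rose 4.60-fold (2.20, SE 0.09), PTPN22, a tyrosine phosphatase, 4.56-fold (2.19, SE 0.09) and SEMA7A, a membrane-anchored semaphorin, 4.03-fold (2.01, SE 0.16). With control siRNA AWAT2 (6.95), MRGPRX4 (5.87) and PTPN22 (6.82) lay below the filter level of 7.29, so their folds and their rank hold for the signal only. The largest falls were those of CEMIP, a hyaluronan-degrading protein, 4.66-fold lower, and DNAJB11, a chaperone of the endoplasmic reticulum, 4.62-fold lower. MPC2, a subunit of the mitochondrial pyruvate carrier, was 4.06-fold lower, GMFB 3.87-fold lower and EDEM3, which acts in the disposal of misfolded glycoproteins, 3.69-fold lower. In each gene of this paragraph all 3 arrays of one group lay above all 3 of the other. The naming rule required this, and it held for 6224 of the 12151 genes tested (51.2%), so it adds no evidence. In all, 4651 of 12151 genes (38.3%) passed the limma test at an adjusted p below 0.05, of which 2483 rose and 2168 fell. Among them 1102 changed by more than 1.5-fold and 286 by more than 2-fold. After cyclic loess 2427 rose and 2253 fell, and with each array centred on its median 2685 rose and 1836 fell.

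Of the 7 tested heme biosynthesis genes, ALAS1 rose and FECH fell (camera adjusted p = 0.578). ALAD, UROS, UROD and CPOX had log2 fold changes from -0.24 to 0.08 and did not pass the test, with adjusted p from 0.0996 to 0.516. UROS (log2 fold change -0.24, adjusted p = 0.252) passed with the runs of sample numbers as a block (adjusted p = 0.0019). PPOX and ALAS2 were below the filter. Of 23 genes of heme and porphyrin transport and breakdown, 7 rose and 6 fell (camera adjusted p = 0.928). Among these ABCB10, a mitochondrial transporter needed for heme synthesis, fell by 0.85 on the log2 scale (SE 0.07), and BACH1, the heme-binding repressor of HMOX1, rose by 0.54 (SE 0.08). ABCG2, which exports porphyrins, had a log2 fold change of 0.27 and did not pass (adjusted p = 0.135). Of 18 iron handling genes, 1 rose, TFRC, and 6 fell (camera adjusted p = 0.158), among them CYBRD1, a ferric reductase, by 1.41 (SE 0.09), the iron importer SLC11A2 by 0.64 (SE 0.09) and ACO1, an iron-regulatory protein, by 0.60 (SE 0.07). Of 20 iron-sulfur cluster genes, 7 rose and 2 fell (camera adjusted p = 0.439), with the mitochondrial chaperone HSPA9 up by 0.49 (SE 0.07).

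Lipid synthesis genes were lower with FECH siRNA. Of 12 fatty acid synthesis genes, 9 fell and 1 rose, with a median log2 fold change of -0.44 (camera adjusted p = 0.0092), and the call was lost with adjusted p = 0.802 with an estimated correlation. The desaturase SCD fell by 0.88 on the log2 scale (SE 0.07), ACSS2, which makes acetyl-CoA from acetate, by 0.61 (SE 0.08) and ACACA, the carboxylase that starts fatty acid synthesis, by 0.59 (SE 0.07). Of 24 genes of cholesterol synthesis and uptake, 11 fell and 1 rose, with a median of -0.24 (camera adjusted p = 0.031, and adjusted p = 0.923 with an estimated correlation). The cholesterol carrier STARD4 fell by 1.15 (SE 0.11), and the synthesis enzyme SQLE by 0.77 (SE 0.21). The cholesterol call ended when FECH siRNA replicate 1 (0.057), FECH siRNA replicate 2 (0.051) or control siRNA replicate 1 (0.064) was left out.

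Among the stress responses, 9 of 26 genes of ATF4 and the integrated stress response rose and 1 fell, with a median log2 fold change of 0.35 (camera adjusted p = 0.037, and adjusted p = 0.923 with an estimated correlation). PPP1R15A, which restores translation after stress, rose 2.18-fold, the transcription factors DDIT3 2.00-fold and ATF3 1.66-fold, and the serine synthesis enzyme PHGDH 1.56-fold. This call was lost with fry, with the sample numbers as a block (camera adjusted p = 0.077) and after cyclic loess (0.053). It was also lost without FECH siRNA replicates 2 (0.051) or 3 (0.097) or control siRNA replicates 1 (0.068) or 3 (0.055). Of 24 targets of NRF2 and BACH1, 9 fell and 4 rose (camera adjusted p = 0.105). Beside HMOX1, those that fell include the exporter ABCC3 1.82-fold lower, the quinone reductase NQO1 1.59-fold lower and GCLM, a subunit of the enzyme that starts glutathione synthesis, 1.45-fold lower. One gene of 22 in the unfolded protein response of the endoplasmic reticulum rose and 2 fell, among them DNAJB11 (camera adjusted p = 0.578). The gene that rose, HSPA5, lost its call in 9 of 17 alternatives, with a limma adjusted p of up to 0.169. Of 15 heat shock genes 4 rose and 2 fell (0.578), with the chaperone HSPH1 1.62-fold lower, and of 15 p53 targets 4 rose and 3 fell (0.880), with TP53INP1 1.97-fold lower. In ferroptosis and glutathione, 2 of 18 rose and 3 fell (0.578), with ACSL4, which activates polyunsaturated fatty acids, 1.36-fold lower.

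In energy metabolism, 8 of 17 glycolysis genes fell and 1 rose (camera adjusted p = 0.159). The gene that rose was hexokinase HK2, 2.25-fold, while the aldolase ALDOC was 1.75-fold lower and lactate dehydrogenase LDHA 1.28-fold lower. Of 19 hypoxia genes 8 fell and 2 rose (0.350), with the prolyl hydroxylase P4HA1 1.93-fold lower and the kinase PDK1 1.61-fold higher. In respiratory complex I, 5 of 34 subunits fell and 2 rose (0.880), with NDUFC2 1.90-fold and NDUFV2 1.79-fold lower. In complexes II to IV, which contain heme, 4 of 27 genes fell and 5 rose (0.928): COX15, which makes heme A, was 1.86-fold lower, UQCR11 of complex III 1.92-fold lower and cytochrome c, CYCS, 1.49-fold higher. None of the 8 tested transcripts of the mitochondrial genome passed the limma test (0.928).

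In inflammation, 5 of 28 interferon response genes fell and 4 rose (camera adjusted p = 0.578), with the chemokine CXCL10 3.09-fold lower and IFIT3 1.53-fold higher. CXCL10 had a log2 signal of at most 7.56 on any array. Its mean with FECH siRNA thus lay below the filter level of 7.29, and its fold holds for the signal only. Of 22 inflammatory cytokines and NF-kB targets 5 rose and 4 fell (0.880), with TNFAIP3, an inhibitor of NF-kB, 2.33-fold higher and IL6 1.73-fold lower. Of 29 mitosis genes 10 rose and 3 fell (0.215), among them the kinase AURKB at 1.48-fold and the proliferation marker MKI67 at 1.35-fold higher, and the kinesin KIF23 at 1.63-fold lower. Of 34 DNA replication genes 8 rose and 5 fell (0.578), with the helicase subunit MCM6 1.42-fold higher and cyclin CCNE2 1.89-fold lower. Of 21 genes of the epithelial to mesenchymal transition 5 rose and 4 fell (0.439), with MMP3 2.85-fold and the transcription factor SNAI2 1.94-fold higher, and ITGB3 2.80-fold lower. Of 14 angiogenic factors 2 rose and 2 fell (0.981), with HBEGF 1.72-fold higher and ANGPT1 1.95-fold lower.

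Among the remaining lists, 4 of 12 genes of small RNA silencing rose and 4 fell (camera adjusted p = 0.826), with DICER1, the nuclease that makes microRNAs, 2.36-fold lower and TNRC6A, a partner of the Argonaute proteins, 1.64-fold higher. Of 25 autophagy and lysosome genes 4 rose and 6 fell (0.578), with the sialidase NEU1 2.27-fold lower and the proton pump subunit ATP6V1A 1.49-fold higher. Of 5 aryl hydrocarbon receptor targets TIPARP rose, 1.87-fold, and NQO1 fell (0.981). Of 4 histone genes H2BC12 rose, 1.57-fold, and H1-2 fell, 1.45-fold lower (0.928). Of the markers of other cell types, 2 of 11 luminal genes rose and 3 fell (0.578), with the keratins KRT18 1.93-fold and KRT8 1.36-fold lower, 1 of 5 fibroblast genes fell, PDGFRB, 1.35-fold lower (0.578), and both tested blood and immune markers fell, PECAM1 2.35-fold and CD14 1.88-fold lower, too few for camera. From 8.47 with control siRNA, PECAM1 fell to just below the filter level of 7.29, so its fold holds for the signal only. Counts of members adjusted over the list alone were the same in 23 of the 30 lists. They differed in the unfolded protein response (0 rose), the interferon response (3 rose), complex I (1 rose), ferroptosis (1 rose), the epithelial to mesenchymal transition (6 rose), angiogenic factors (1 rose) and small RNA silencing (5 fell). Of the 29 tested lists 3 passed with camera and 0 with an estimated correlation, while 12 passed with fry, whose lowest adjusted p was 1.1e-04 for the targets of NRF2 and BACH1 and for fatty acid synthesis.

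The comparison of 5-ALA with no treatment asks what 5-ALA does without transfection. HMOX1 rose from 8.68 ± 0.15 to 10.69 ± 0.26 on the log2 scale (SD, n = 3), 4.03-fold higher (limma adjusted p = 7.9e-06). FBXO30, which encodes an F-box protein of ubiquitin ligases, rose from 9.85 ± 0.14 to 10.62 ± 0.04 (SD, n = 3; probe set 8130032), 1.70-fold higher (limma adjusted p = 9.3e-04). For both genes all 3 arrays with 5-ALA lay above all 3 untreated ones. ALAS1 was at 9.46 ± 0.25 without and 8.71 ± 0.13 with 5-ALA (SD, n = 3), a log2 fold change of -0.76 that did not pass (limma adjusted p = 0.054). FECH, with a log2 fold change of 0.01, and ALAD (-0.01), UROS (0.00), UROD (0.03) and CPOX (0.22) did not pass either, nor did TFRC (-0.03) and ABCG2 (0.11).

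HMOX1 and FBXO30 were the only 2 of 12151 genes past the limma test, and 343 genes had an unadjusted p below 0.05 (711 with the sample numbers as a block), where 608 would be expected with no effect if the samples were independent. ALAS1 passed in 7 of 16 alternatives, among them the sample numbers as a block (adjusted p = 0.026), array weights (0.012) and leaving out untreated replicate 2 (0.043) or 3 (0.048), and its highest adjusted p was 1.00 in a fit of only these 2 groups. Adjusted over the list alone it was the 1 heme biosynthesis gene that fell. FBXO30 was lost in a fit of only these 2 groups (adjusted p = 0.057). The further genes with the lowest unadjusted p were, among those higher with 5-ALA, GCLM (log2 fold change 0.47), the clock gene BMAL1 (0.31), SPATA31G1 (0.35), TATDN1 (0.35) and UNKL (0.23), and among those lower, after ALAS1, WDR38 (-0.28), BEND3 (-0.27), AQP7 (-0.31) and HSPA2 (-0.25), none past the test.

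As a group, the targets of NRF2 and BACH1 were higher with 5-ALA (camera adjusted p = 0.0029, and adjusted p = 0.306 with an estimated correlation), with a mean log2 fold change of 0.15 but a median of 0.03, and HMOX1 at 2.01. Of the 24 tested, 1 rose over all genes, HMOX1, and 2 rose adjusted over the list alone. Camera also placed the 26 genes of ATF4 and the integrated stress response higher (adjusted p = 2.0e-07, median log2 fold change 0.21), the 5 aryl hydrocarbon receptor targets higher (0.029, median 0.48) and the 19 hypoxia genes lower (9.7e-05, median -0.08). No member of these 3 lists passed the limma test, over all genes or adjusted over the list alone, and each list gave adjusted p = 0.655 with an estimated correlation. None of the 3 lists passed with fry. One array, untreated replicate 3, stood apart from its group. On the log2 scale 416 of its genes lay more than 0.5 from the mean of the other 2 untreated arrays. The same count was 10 to 115 for the other arrays within their groups. Without it the 3 calls ended, with adjusted p = 0.336 for ATF4, 0.453 for hypoxia and 0.733 for aryl hydrocarbon receptor targets. The last also ended with no filter (0.177) and without 5-ALA only replicate 1 (0.123) or replicate 2 (0.238).

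The comparison of control siRNA with 5-ALA only asks what transfection with an siRNA does under 5-ALA. CMKLR1, the receptor of chemerin, rose 2.15-fold (log2 fold change 1.10, SE 0.09, n = 3), the serotonin receptor HTR1D 2.04-fold (1.03, SE 0.14) and follistatin, FST, which binds activin, 1.96-fold (0.97, SE 0.14). SMIM15 fell, 2.52-fold lower, as did the phosphatases BPNT2, 2.49-fold lower, and MINPP1, 2.03-fold lower. PTX3, a secreted pattern recognition protein, was 2.47-fold lower and GNPNAT1, an enzyme of UDP-GlcNAc synthesis, 2.26-fold lower. With control siRNA PTX3 (7.25) lay just below the filter level of 7.29, so its fold holds for the signal only. FECH (log2 fold change 0.05), ALAS1 (0.04), TFRC (0.14) and ABCG2 (-0.19) did not pass. HMOX1 (-0.36, adjusted p = 0.121) passed with the sample numbers as a block (adjusted p = 0.035), with array weights and without 5-ALA only replicate 1 (0.036), and CPOX (-0.23, adjusted p = 0.372) passed with the block (adjusted p = 0.031).

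In this comparison 753 genes passed the limma test, of which 306 rose and 447 fell, and 74 changed by more than 1.5-fold. With the runs of sample numbers as a block 1652 passed, of which 737 rose and 915 fell. With each array centred on its median 170 rose and 537 fell, so that the share of rises was 24.0% in place of 40.6%. The count was 426 without 5-ALA only replicate 1, 487 without replicate 2 and 367 without replicate 3, and it was 493, 350 and 426 without control siRNA replicates 1, 2 and 3. Over all probe sets 496 passed.

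Most lists had few members past the test in this comparison. Genes of ATF4 and the integrated stress response were lower as a group (camera adjusted p = 0.019, median log2 fold change -0.20, and adjusted p = 0.950 with an estimated correlation), though only PHGDH of 26 fell, over all genes and adjusted over the list alone, 1.40-fold lower. That call ended with fry, after cyclic loess (0.054) and without control siRNA replicate 1 (0.069). Of 5 fibroblast markers PDGFRB rose 1.26-fold and the collagen COL1A1 1.22-fold (camera adjusted p = 0.019, and adjusted p = 0.323 with an estimated correlation), and 3 rose adjusted over the list alone. The fibroblast call ended after cyclic loess (0.054) and without 5-ALA only replicate 3 (0.054). PDGFRB passed without 2 of the 6 arrays left out in turn and COL1A1 without 1 of them. Among other list members, HK2 was 1.49-fold, ATP6V1A 1.49-fold, MMP1 1.57-fold and the p53 inhibitor MDM2 1.42-fold lower, and NEU1 was 1.39-fold and the aldo-keto reductase AKR1C3 1.48-fold higher.

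The comparison of FECH siRNA with 5-ALA only joins the effects of transfection and of the FECH siRNA. HMOX1 fell, 4.08-fold lower (log2 fold change -2.03, SE 0.13, n = 3), and ALAS1 rose 2.25-fold (1.17, SE 0.11) and TFRC 1.38-fold (0.46, SE 0.08). AWAT2 rose 7.28-fold, MRGPRX4 6.10-fold, SEMA7A 4.91-fold, the neutrophil collagenase MMP8 4.23-fold and the transcriptional repressor PRDM1 3.66-fold. CEMIP fell, 5.98-fold lower, as did OLR1, a receptor of oxidized low-density lipoprotein, 5.06-fold lower, LIN7C 4.63-fold lower and ETFDH, which passes electrons to ubiquinone, 3.99-fold lower. AWAT2 (6.68), MRGPRX4 (5.73) and MMP8 (7.11) with 5-ALA only and ETFDH (6.74) with FECH siRNA lay below the filter level, so their folds hold for the signal only. In each gene of this paragraph all 3 arrays of one group lay above all 3 of the other.

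In all, 4495 genes passed the limma test, of which 2366 rose and 2129 fell, and 1037 changed by more than 1.5-fold. After cyclic loess 2177 rose and 2311 fell, and with each array centred on its median 2079 rose and 2101 fell. The excess of rises therefore depended on the normalization. Of 12 fatty acid synthesis genes 7 fell and 0 rose, and 8 fell adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.944 with an estimated correlation). They include SCD, 1.67-fold lower, ACACA, 1.58-fold lower, and the fatty acid synthase FASN, 1.32-fold lower. This was the 1 list past camera, and the lowest adjusted p of the others was 0.170. Of the heme biosynthesis genes, CPOX (log2 fold change -0.36, adjusted p = 0.060) passed in 4 of 17 alternatives, among them the sample numbers as a block (adjusted p = 6.1e-04) and leaving out untreated replicate 3 (0.018), and UROS (-0.19, adjusted p = 0.393) passed with the block (adjusted p = 0.0092). CYBRD1 was 2.41-fold lower, GCLM 1.77-fold lower and ACSL4 1.77-fold lower, and MMP3 was 3.11-fold and N-cadherin, CDH2, 1.64-fold higher.

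Of the 4651 genes that passed against control siRNA, 3396 (73.0%) passed in the same direction against 5-ALA only, 1770 of them higher and 1626 lower, and 24 passed the other way. These comparisons share the FECH siRNA arrays, so part of the overlap can come from them. Chance for independent comparisons would give 483 shared rises and 380 shared falls. Simulated arrays with no effect but the same shared arrays gave 0 of either. Without any effect hardly a gene passes, so this 0 does not show how much of the overlap the shared arrays bring. The log2 fold changes of both comparisons correlated across genes at 0.893, against 0.502 in the simulations, where genes are not independent replicates.

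HMOX1, ALAS1 and FBXO30 were also compared with untreated cells, in comparisons added after the data had been seen. HMOX1 with FECH siRNA and 5-ALA differed from untreated cells by -0.02 on the log2 scale (95% confidence interval -0.29 to 0.26, limma adjusted p = 0.934), while with control siRNA and 5-ALA it was 3.14-fold higher than in untreated cells (limma adjusted p = 2.3e-05). ALAS1 was 1.33-fold higher than in untreated cells with FECH siRNA (limma adjusted p = 0.010) and 1.64-fold lower with control siRNA (limma adjusted p = 0.0026). FBXO30, chosen after its values were seen in these comparisons, was 1.45-fold higher with control siRNA (limma adjusted p = 0.0014), had a log2 fold change of 0.11 with FECH siRNA (limma adjusted p = 0.298), and was 1.34-fold lower with FECH siRNA than with control siRNA (limma adjusted p = 5.8e-04).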

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

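The tests of a response to the control siRNA alone, of transfection as such and of the ATF4 list without 1 array, and the counts of other splits set beside the genes opposed by FECH siRNA, were chosen only after the results they concern had been seen, as were the comparisons with untreated cells behind them.

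Probe sets with no gene symbol or with several were left out of the comparisons, and many of these 8932 passed the limma test when tested apart. For FECH siRNA against control siRNA 558 passed, 264 higher and 294 lower, of which 179 carry no symbol. For FECH siRNA against 5-ALA only 481 passed, and for control siRNA against 5-ALA only 34 did.

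The response to FECH siRNA covered 38.3% of the genes tested, and 3 technical or indirect causes were tested. After cyclic loess between arrays, which moved the log2 values by 0.019 in absolute size on average, 4680 genes passed in place of 4651. This argues against a shift left between arrays of the kind that cyclic loess removes. Both steps bring the arrays towards each other, so a shift made by the authors' normalization itself was not tested. The lowest count with 1 array left out was 3810, which argues against a single array. Of the genes past the test, 73.0% passed the same way against 5-ALA only, which argues against a response to the control siRNA alone, although the shared FECH siRNA arrays add to this share. Of the 10 splits of the 6 arrays 1, the real one, gave as many genes. The highest of the others gave 0, also among the 4 that part every pair of sample numbers. Every other split mixes both groups, so a difference between them widens its spread and lowers its count. For that reason, and because 10 splits are too few for a share under 0.05, the splits decide nothing. Because 1 siRNA sequence was used, loss of FECH and matches of this siRNA to other transcripts both stay open, and the latter was not tested.

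HMOX1 and FBXO30 were higher with 5-ALA and lower with FECH siRNA, and ALAS1 showed the opposite values. The lowest log2 fold change of HMOX1 with 5-ALA when 1 of the 6 arrays was left out was 1.90, which argues against a single array, and HMOX1 was 1.65 higher on the log2 scale with control siRNA than without treatment, which argues against an effect of transfection as such. Whether FECH siRNA opposed the response to 5-ALA at large stays open: of 340 other genes with an unadjusted p below 0.05 with 5-ALA, 40% had the opposite sign with FECH siRNA (41.7% of 708 with the sample numbers as a block), against 46.4% of all genes, but 1 of the 3 other splits that part every pair gave 506 genes at such a p against 343 in the real one (1024 against 711 with the block), so their number does not stand out and their signs decide nothing. HMOX1 and ALAS1 are regulated by heme in opposite directions, so the values are consistent with less heme being made from 5-ALA when FECH is low, a hypothesis only, since heme was not measured. The count of genes past the test with 5-ALA was reached by 1 of 10 splits, the real one. The highest other gave 0, also among the 4 that part every pair. The other splits mix both groups, which widens their spread, and they are too few for a share under 0.05, so they decide nothing.

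Untreated replicate 3 stood apart from the other untreated arrays, with an array weight of 0.363 against 0.696 to 2.51 in the other arrays. Without it the ATF4 list gave a camera adjusted p of 0.336 in 5-ALA against no treatment, against 2.0e-07 with it and 6.6e-13 to 5.9e-05 with each of the other 5 arrays left out, so this array alone may carry that shift. For the ATF4 list, a difference shared by its run of sample numbers is argued against by the other 3 arrays of that run. Their mean deviation of this list from their group means was 0.036 (SD 0.035). Over all genes, however, untreated arrays deviated together with arrays of the same run in other groups, at correlations of 0.250 to 0.514. On the second principal component replicate 3 was the lowest of its group in each of the 4 groups. A shared difference outside the ATF4 list therefore stays open. The labels give no handling, date or culture for untreated replicate 3, so its state before RNA extraction stays open, and no biological explanation was tested.

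For control siRNA against 5-ALA only and for FECH siRNA against 5-ALA only, 753 and 4495 genes passed. In each case 1 of the 10 splits, the real one, gave as many genes and the highest other gave 0, also among the 4 that part every pair. Here too the other splits mix both groups and are too few for a share under 0.05, so they decide nothing.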

How the results depend on the processing

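The settings without untreated replicate 3 for the comparisons it is not part of were chosen after the data had been seen, and the others were planned. The counts for FECH siRNA against control siRNA and against 5-ALA only stayed within 1.5 times under every alternative run, at 3721 to 5683 and at 3586 to 5582. The number tested differed, so the share past the test was less stable than the count. Against control siRNA, 3721 of 7829 genes passed with the 70th-percentile filter, 4806 of 19117 with no filter, and 5149 of 28869 probe sets. FECH kept its direction and its call in both comparisons under each of the 15 alternatives run for it, which leave out the 2 other filters. For 5-ALA against no treatment, 1 gene passed in a fit of only the 2 groups, where fewer samples estimate the spread, and 2 or 3 passed under the other alternatives. For control siRNA against 5-ALA only, 1652 genes passed with the run of sample numbers as a block, which takes the spread between runs out of the error, and 496 over all probe sets, where more are tested, and leaving out an array of either group gave 350 to 493, where fewer samples are compared, and 1032 passed without untreated replicate 3.

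Of 3126 alternatives for 187 results on named genes, 3058 stayed on the same side of the test, 51 lost the call, 17 gained it and 0 reversed. Of 1392 for 116 results on lists, 1323 stayed on the same side, 34 lost the call, 33 gained it and 2 reversed. The interferon response list, higher with 5-ALA and not past the test, was lower and past it without untreated replicate 3 (adjusted p = 0.042, and 0.142 to 0.949 with each other array left out), and the list of inflammatory cytokines and NF-kB targets was lower and past it without 5-ALA only replicate 3 (0.022, and 0.263 to 0.868 with the others). The cause was not tested. No list call held with an estimated correlation. FECH has 1 probe set, so testing each of its probe sets on its own moved nothing. Camera takes no robust variance, so lists were run with the trend alone. Signal over background limits what was tested, since the filter kept 12151 genes of 19117.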

Other observations

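The zinc finger family, the genes of untreated replicate 3 and the genes that moved in opposite directions were chosen after their values were seen, and so were their tests.

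Genes of the ZNF-numbered zinc finger family, which encode mostly DNA-binding repressors, were more often higher than lower with FECH siRNA. Of 332 tested, 100 rose and 31 fell against control siRNA, with a median log2 fold change of 0.06 (camera p = 0.0010, and p = 0.103 with an estimated correlation), and the direction was the same after cyclic loess (camera p = 2.8e-04). Against 5-ALA only 89 rose and 29 fell (camera p = 0.0049, and p = 0.153 with an estimated correlation). None of the 332 passed the limma test for 5-ALA against no treatment, where their median was 0.05 (camera p = 0.0064, and p = 0.165 with an estimated correlation). With control siRNA against 5-ALA only 6 rose and 11 fell, with a median of -0.01 (camera p = 0.214, and p = 0.506 with an estimated correlation).

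Some genes moved one way with control siRNA against 5-ALA only and the other way with FECH siRNA against control siRNA. This held for 411 genes, against 95 that moved the same way, and since the control siRNA arrays enter both comparisons with opposite sign, part of this comes from them. The log2 fold changes of both comparisons correlated across genes at -0.284, against -0.497 in simulated arrays with no effect but the same shared arrays, where genes are not independent replicates. Their covariance was -0.0167 against -0.00485 in the simulations, so the correlation was weaker and the covariance larger than the shared arrays alone gave, and the share of the 411 that the shared arrays explain was not tested. PTX3 was 2.47-fold lower with control siRNA than with 5-ALA only, and its log2 fold change with FECH siRNA against control siRNA was 1.92. Both changes hold for the signal only, since PTX3 with control siRNA (7.25) lay just below the filter level. TMEM156 was 1.98-fold lower with control siRNA, and its change with FECH siRNA was 1.77. PTX3 and TMEM156 were chosen after their values were seen in the second comparison.

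In untreated replicate 3, CYP1A1, a target of the aryl hydrocarbon receptor, had a log2 signal of 6.79, against 10.08 to 11.82 in the other 11 arrays. CYP1B1, a target of the same receptor, was at 10.70 against 12.66 to 12.91. The ATF4 targets CHAC1 and SESN2 were at 8.31 against 10.17 to 10.62 and at 7.99 against 9.57 to 10.62. The cytokine IL11 was at 10.41 against 8.23 to 9.05.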
